A study of Escherichia coli with 12 samples.

How the data were processed

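RNA sequencing libraries were made from 12 samples of *Escherichia coli* HS, a commensal strain, in 3 groups of 4 named in the labels. Per the labels' protocols, the bacteria were grown aerobically at 37 °C and 200 rpm in tissue culture medium with 10% heat-inactivated serum, RNA was purified and depleted of ribosomal RNA, and libraries were made with a kit that does not mark strand. Genes that overlap or lie antisense therefore cannot be told apart by strand. The strand setting of the counting is not given in the sources used here. The submitters' processing notes name Trim Galore, STAR, featureCounts, edgeR, DESeq2 and DESeq, and their versions and roles, the genome build and the annotation are not given in the sources used here.

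The authors deposited a table of raw counts per gene, which are whole numbers, for 3315 genes and 12 libraries. The authors also deposited a table of normalized signal, which equals the raw counts multiplied by 1 factor per library with a relative deviation of at most 4.9e-15, next to p-values and adjusted p-values of their own and log2 fold changes. The deposited p-values and log2 fold changes were used only to set the calls beside those made here. Genes with few counts had been removed before deposition, since every gene in the table reached at least 7.04 CPM in 4 libraries. Of the 3315 genes, 3032 carried a symbol and 47 shared theirs with another gene, and no row carried a ribosomal RNA symbol. Gene names were taken from the table itself, and no coordinates are printed because a genome of this strain was not used here.

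Changes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. The quasi-likelihood test was fitted to all 12 libraries with 1 coefficient per group and TMM factors, and p-values were adjusted over the 3315 genes by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change is the one implied by that test, and intervals are at the 95% level. Values of single genes are CPM after TMM scaling, with the SD over 4 libraries. The filter of edgeR for low counts removed 0 genes.

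Before the data were examined, the groups, tests, alternatives, the 34 gene lists and the rule for named genes were written down. The rule takes, per comparison, the 5 genes with the largest increase and the 5 with the largest decrease among those with an adjusted p under 0.05, a symbol, a mean of at least 10 CPM and no overlap between the libraries of the groups. It adds the 2 most changed members of the 6 lists with the largest share of changed members (at least 3 changed). It also adds 12 genes tied to the added metabolites, named whatever their values: *purC* (ECHS_RS12890), *purH* (ECHS_RS20865), *guaB* (ECHS_RS13125), *deoD* (ECHS_RS22765), *ushA* (ECHS_RS02755), *speE* (ECHS_RS00620), *puuA* (ECHS_RS06965), *mdtJ* (ECHS_RS08315), *glpD* (ECHS_RS17840), *fbaB* (ECHS_RS11060), *uhpT*, which was not analysed here, and 1 gene that is not reported here. Genes named beyond the rule were chosen after their values were seen.

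The lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an estimated correlation between genes, for lists with at least 3 members in the table. Of 616 list members, 103 were not analysed here. Alternatives were camera with a preset correlation of 0.01 and fry. The number of changed members of each list is given over all genes tested and adjusted over the list alone. Library measures were compared by exact two-sided permutation tests over the 70 labelings of 4 against 4 libraries.

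Other settings were RLE factors, upper-quartile factors, library totals only, DESeq2 1.42.0, limma voom, a filter of 10 CPM in 4 libraries, only the 8 libraries compared, the replicate number as a block, a 2-fold threshold and each library left out in turn. A setting with the 10 most counted genes removed was chosen after seeing the data. A setting with no filter was void, since no gene was removed by the filter used, and one without ribosomal RNA was not run because no row carried such a symbol.

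The tests were checked on simulated counts for the 3315 genes, with 200 genes changed by known folds. At 1.2-fold, 1.5-fold, 2-fold and 4-fold, edgeR recovered 20, 88, 96 and 100% of the changed genes for MM6 against control, 16, 70, 98 and 100% for MM3 against control, and 14, 86, 98 and 100% for MM6 against MM3. The fold of 1.2 replaced a larger one after the first simulated results had been seen. False calls made up 5.59, 4.7 and 3.25% of all calls in these comparisons. For lists, each of the 3 methods called the 3 lists shifted 1.5-fold in each comparison. Of the lists that were not shifted, the preset correlation and fry each called 1 for MM6 against control. The simulated genes were drawn independently of one another, where the estimated correlation in the real lists had a median of 0.187. The check therefore does not show how often these methods call or miss lists whose genes correlate. The libraries held 6676778 to 8535501 counts in control, 7090233 to 10209672 in MM3 and 7360791 to 11166478 in MM6, and the common biological coefficient of variation was 0.114. The authors' deposited table had 1838, 1225 and 1792 genes with an adjusted p under 0.05 in the comparisons of MM6 with control, MM3 with control and MM6 with MM3, and 1777, 1141 and 1711 of these were called in the same direction here.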

Results

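Messenger RNA was measured by RNA sequencing in *Escherichia coli* HS, a commensal strain, grown with shaking in tissue culture medium containing serum. The 12 libraries formed 3 groups of 4. The control group was grown in medium alone. The group called MM6 received a mixture of 6 metabolites, namely the polyamine spermidine, the purine nucleotides GMP and IMP, the glycolytic intermediates fructose 1,6-bisphosphate and dihydroxyacetone phosphate, and UDP-glucose. The group called MM3 received spermidine, GMP and IMP, which are 3 of those 6 metabolites. Their concentrations are not given in the sources used here. The cultures were sampled in the middle of exponential growth, at a point which the submitters placed before any difference in growth. The deposited table held 3315 genes, and the libraries held 6676778 to 11166478 counts each. Nothing in the labels states that the 4 replicates of a group came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

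The libraries separated by group. On the first principal component of log2 CPM, which held 54.0% of the variance, the MM6 libraries lay between 20.57 and 21.06, the MM3 libraries between -9.13 and -4.55 and the control libraries between -16.7 and -13.2. The second component, with 24.1% of the variance, set the MM3 libraries (-14.6 to -11.9) apart from the other 8. Ribosomal protein genes took 9.53% ± 0.404 (SD, n = 4) of the counts in control, 13.4% ± 1.10 in MM3 and 14.4% ± 0.535 in MM6. The transfer-messenger RNA gene *ssrA* took 13.1% ± 1.54, 14.6% ± 1.17 and 10.1% ± 0.824, and the cold shock protein gene *cspA* took 5.34% ± 0.464, 6.23% ± 0.253 and 7.09% ± 1.29. In exact two-sided permutation tests of 4 against 4 libraries, the ribosomal protein share differed from control with p = 0.0286 in both mixtures, the smallest value this design can give, and with an adjusted p of 0.0536 over 15 tests of library measures, so no such measure passed the correction. MM6 replicate 2 stood apart from its group on the third component (8.96% of the variance, -17.1 against 2.7 to 7.95). Its share of *rnpB*, the RNA of ribonuclease P, was 0.572% against 1.97 to 2.72% in the other MM6 libraries. All 12 libraries were kept.

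**Figure D1:**
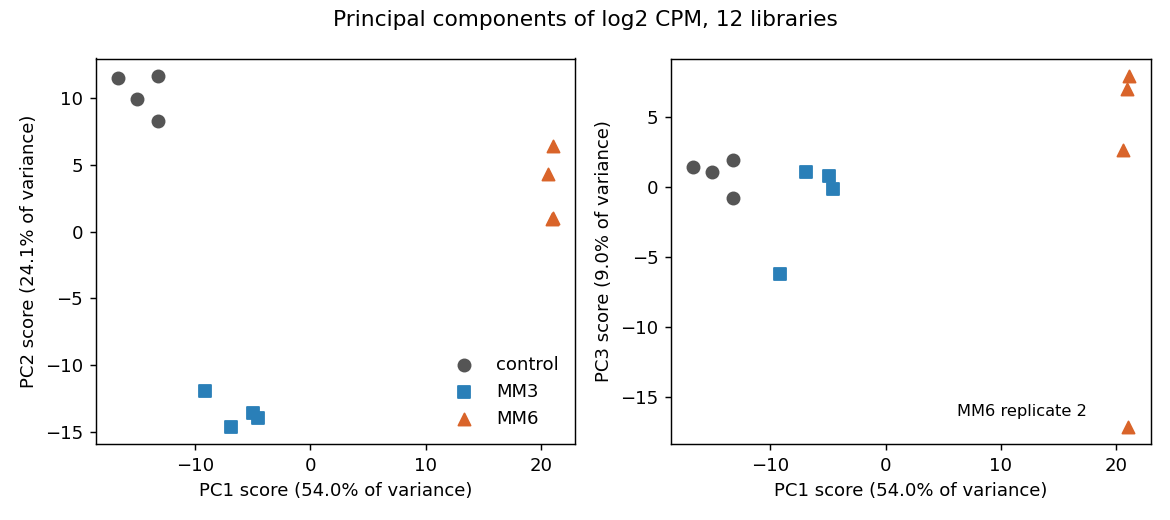
Scores of the 12 libraries on the first principal component of log2 CPM against the second (left) and the third (right), with 1 point per library and the share of variance on each axis. The MM6 libraries lie at 20.57 to 21.06 on the first component, and MM6 replicate 2 lies at -17.1 on the third.

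The first comparison asked what the 6 metabolites together did to transcription. With MM6, 11 of 14 purine synthesis genes fell, and 21 of 24 genes of anaerobic respiration and fermentation and 53 of 54 ribosomal protein genes rose. None of these lists was called by limma's camera test (adjusted p = 0.243 with an estimated correlation for each). List members named beyond the rule for named genes, here and in the other comparisons, were chosen after their values were seen. Under the naming rule, which asks for a mean of at least 10 CPM and no overlap between the libraries of the groups, the largest increases were in *napH* (log2 fold change 3.83 ± 0.23, SE, n = 4 per group), *napB* (3.53 ± 0.14) and *napA* (3.04 ± 0.15), which encode parts of the periplasmic nitrate reductase, in *nikC* (3.36 ± 0.28), a permease of the nickel transporter, and in *ubiU* (2.91 ± 0.18), needed for ubiquinone synthesis without oxygen. For *napA* (ECHS_RS11620) this was a change from 14.6 ± 1.80 CPM (SD) in control to 120.1 ± 15.9. The others had lower control means, of 1.69 CPM for *napH*, 3.18 for *napB*, 2.80 for *nikC* and 5.20 for *ubiU*. They reached the mean of 10 CPM set by the rule only through MM6. The largest decreases under that rule were in *purC* (-2.50 ± 0.08), *purM* (-2.43 ± 0.12), *purT* (-2.29 ± 0.14), *purN* (-2.22 ± 0.08) and *purL* (-2.20 ± 0.12), all enzymes on the path to IMP, and *purC* (ECHS_RS12890) went from 642 ± 19.2 to 114 ± 9.99 CPM. By edgeR's quasi-likelihood test the adjusted p of these 10 genes lay between 5.86e-12 for *purC* and 9.23e-08 for *nikC*.

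In all, 1782 of 3315 genes (53.8%) changed at an adjusted p under 0.05, of which 898 were higher and 884 lower with MM6, and 320 changed at least 2-fold (173 higher, 147 lower). With scaling by library totals only, which shifted the median log2 fold change of all genes by -0.19, the split was 571 higher and 1384 lower. At an unadjusted p under 0.05 there were 1966 genes, and without MM6 replicate 2 the test called 1964.

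Of the genes tied to the nucleotides added, 11 of 14 purine synthesis genes were lower with MM6 and 3 did not pass (11 lower when adjusted over the list alone, adjusted p = 0.243 with an estimated correlation, by limma's camera test). The 3 were *guaA*, *purA* and *guaB*, which lie after IMP on the branches to AMP and GMP; *guaB*, the IMP dehydrogenase gene, had a log2 fold change of 0.06 ± 0.09 (95% interval -0.125 to 0.249), -0.13 with library totals only and -0.027 without MM6 replicate 4. Among 18 genes of purine salvage and nucleoside use, 8 were higher and none lower, also adjusted over the list alone (adjusted p = 0.243 with an estimated correlation), and 5 were higher and 4 lower with library totals only. Without control replicate 1, MM6 replicate 2 or MM6 replicate 3, 1 was lower. The genes that rose included *deoB* (1.62 ± 0.07), *deoD* (1.35 ± 0.08), the purine nucleoside phosphorylase gene, and *add* (1.13 ± 0.08), the adenosine deaminase gene. The 5'-nucleotidase gene *ushA* had a log2 fold change of -0.05 ± 0.08 (adjusted p = 0.59 in edgeR), which became -0.24 (adjusted p = 0.049) with library totals only.

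Of the genes tied to spermidine, all 9 polyamine breakdown genes tested were lower with MM6 (9 adjusted over the list alone, adjusted p = 0.243 with an estimated correlation). Without MM6 replicate 2, 7 of the 9 were called lower. With all libraries, the largest changes were in *puuA* (-2.08 ± 0.14), whose product starts putrescine breakdown, and *puuC* (-2.07 ± 0.24). Of 5 polyamine synthesis genes 4 were higher (4 adjusted over the list alone, adjusted p = 0.381 with an estimated correlation), but 1 was higher with library totals only. The spermidine synthase gene *speE* (0.35 ± 0.10, adjusted p = 0.0061 in edgeR) was not called with library totals only (0.15, adjusted p = 0.124). Of 11 genes for polyamine transport and acetylation 5 were higher and 3 lower, also adjusted over the list alone, and 2 and 4 with library totals only (adjusted p = 0.901 with an estimated correlation; the median of -0.01 and the test differed in sign). The putrescine importer gene *plaP* rose (1.62 ± 0.12), and *mdtI* (-1.13 ± 0.14) and *mdtJ* (-1.21 ± 0.13), which together encode a spermidine exporter, fell.

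Of the genes tied to the sugar phosphates and UDP-glucose, 7 of 12 glycolysis genes were higher and 2 lower with MM6, also adjusted over the list alone (adjusted p = 0.585 with an estimated correlation), 4 were higher with library totals only, and 1 to 2 were lower over the other scalings. The genes that rose included *gpmM* (0.88 ± 0.07) and *pykF* (0.78 ± 0.15), the phosphoglycerate mutase and pyruvate kinase genes. The class I fructose bisphosphate aldolase gene *fbaB* fell (-0.86 ± 0.12, adjusted p = 2.98e-05 in edgeR). Of 9 gluconeogenesis genes 6 were lower and 1 was higher, also adjusted over the list alone (adjusted p = 0.328 with an estimated correlation), with *aceB* (-1.14 ± 0.11) of the glyoxylate bypass lowest. Of 13 genes for the uptake of glycerol and phosphorylated sugars 3 were higher, namely the hexose phosphate sensor and regulator genes *uhpA* (1.04 ± 0.22), *uhpB* (1.22 ± 0.23) and *uhpC* (1.09 ± 0.17), and 5 were lower, also adjusted over the list alone (adjusted p = 0.819 with an estimated correlation); 3 were lower without control replicate 4 or MM6 replicate 4. The transporter gene *uhpT* was not analysed here. The glycerol 3-phosphate dehydrogenase gene *glpD* did not pass the test (-0.20 ± 0.11, 95% interval -0.436 to 0.0358), and was called with library totals only (-0.39, adjusted p = 0.0148).

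Of 24 genes for anaerobic respiration and fermentation 21 were higher with MM6, 3 did not pass and none was lower (21 adjusted over the list alone, adjusted p = 0.243 with an estimated correlation). The list holds 40 genes, and the others were not tested in any comparison. Every deposited gene reached 7.04 CPM in 4 libraries, which MM6 alone can supply, as for *frdD* (mean 4.44 CPM in control, 5.03 in MM3, 25.6 in MM6). Genes low in every group may be missing, so the share is not that of the whole list. The changes of the tested genes reached 2.51 ± 0.19 for *frdD* and 2.28 ± 0.21 for *frdC*, the membrane anchors of fumarate reductase, and the pyruvate formate-lyase gene *pflB* was at 1.29 ± 0.14. Of 54 ribosomal protein genes 53 were higher (53 adjusted over the list alone, adjusted p = 0.243 with an estimated correlation), with a median log2 fold change of 0.85 and the largest changes in *rpmE* (1.33 ± 0.12) and *rpsU* (1.27 ± 0.13); the ribosomal protein share of all counts in these libraries is given above. Of 29 aerobic respiratory chain genes 15 were higher and 2 lower, also adjusted over the list alone (adjusted p = 0.531 with an estimated correlation), and 14 and 8 with library totals only; all 13 *nuo* genes of NADH dehydrogenase in the list were among the higher ones.

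Of 15 heat shock genes 14 fell with MM6 (14 adjusted over the list alone, adjusted p = 0.243 with an estimated correlation), led by the chaperone genes *groL* (-1.04 ± 0.07) and *dnaK* (-1.04 ± 0.08). Of 16 general stress genes 11 fell (11 alone, adjusted p = 0.357 with an estimated correlation), including *rpoS* (-0.68 ± 0.10), the stationary phase sigma factor. Of 17 oxidative stress genes 10 fell and 3 rose, and of 11 acid stress genes 7 fell, all counts being equal when adjusted over the list alone (adjusted p = 0.243 and 0.539 with an estimated correlation); 4 acid stress genes fell without MM6 replicate 1 or MM6 replicate 3. All 6 iron-sulfur cluster assembly genes *sufA* to *sufE* and *sufS* were among the oxidative stress genes that fell, for instance *sufC* (-1.31 ± 0.09) and *sufS* (-1.19 ± 0.10), while *katG* rose (0.79 ± 0.08). With library totals only, 1 oxidative stress gene rose. In branched-chain amino acid synthesis 10 of 12 genes fell and 1 rose, and in nitrogen limitation 11 of 13 fell, again also adjusted over the list alone (adjusted p = 0.381 and 0.243 with an estimated correlation). Examples were *ilvD* (-0.90 ± 0.16) and *leuC* (-0.85 ± 0.09), and the arginine breakdown genes *astA* (-2.37 ± 0.28) and *astC* (-1.76 ± 0.21).

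**Figure D2:**
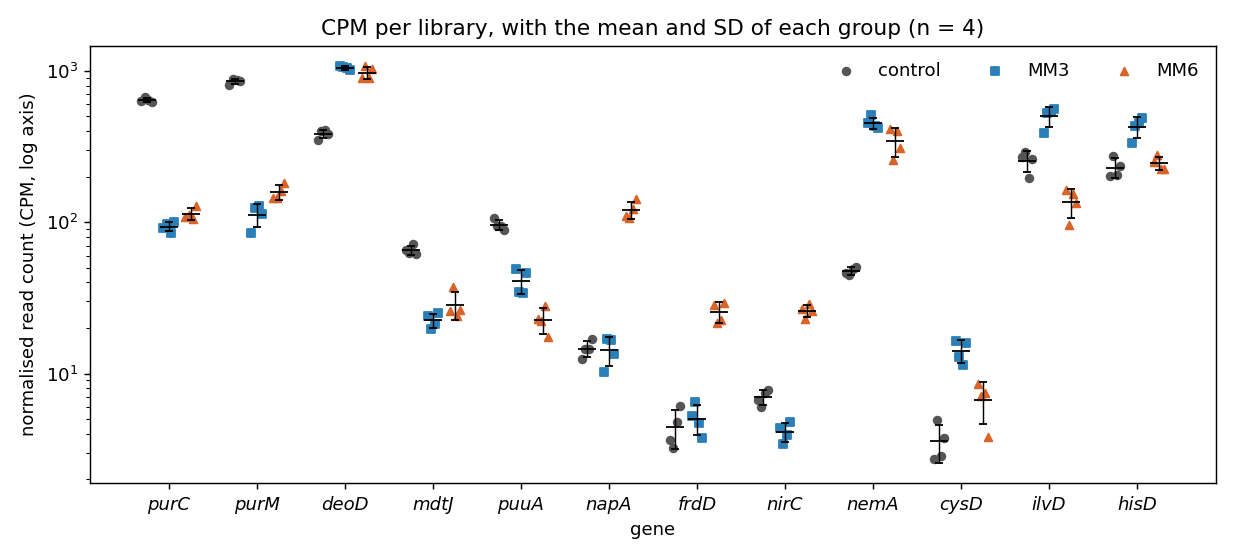
Normalised read count (CPM, log axis) of 12 named genes in every library, with points for the 4 libraries of each group and a bar for the mean and SD of the group. *napA* has a mean of 14.6 CPM in control, 14.4 in MM3 and 120.1 in MM6, and *purC* has 642, 93.6 and 114.

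The second comparison asked what the 3 metabolites alone did. With MM3, 11 of 14 purine synthesis genes fell, and 52 of 54 ribosomal protein genes and all 7 histidine synthesis genes rose. None of these lists was called by camera (adjusted p = 0.176, 0.204 and 0.365 with an estimated correlation). Under the naming rule, the decreases were largest in *purM* (-2.92 ± 0.12), *purK* (-2.83 ± 0.12), *purT* (-2.83 ± 0.14) and *purC* (-2.78 ± 0.08) and in *xanP* (-2.80 ± 0.22), a xanthine importer gene (log2 fold change with SE, n = 4 per group). The largest increases under that rule were in *nemA* (3.25 ± 0.14), an N-ethylmaleimide reductase gene, and its repressor gene *nemR* (2.02 ± 0.12), in *tcyP* (2.26 ± 0.26), a cystine importer gene, in *bhsA* (2.26 ± 0.15), which encodes an outer membrane stress protein, and in *ymgD* (2.10 ± 0.35). *nemA* (ECHS_RS08575) went from 47.7 ± 2.84 CPM (SD) in control to 453 ± 38.4. The adjusted p of these 10 genes by edgeR lay between 2.12e-12 for *purC* and 0.000296 for *ymgD*.

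In all, 1151 genes (34.7%) changed, 545 higher and 606 lower, and 118 changed at least 2-fold (56 higher, 62 lower). With scaling by library totals only, which shifted the median by -0.22, the split was 274 higher and 1373 lower. At an unadjusted p under 0.05 there were 1468 genes, and without MM6 replicate 2, which enters the shared estimate of spread, the test called 1488.

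Of 14 purine synthesis genes 11 were lower with MM3, *guaA*, *guaB* and *purA* again not passing (11 lower and 1 higher adjusted over the list alone, adjusted p = 0.176 with an estimated correlation). *purH*, which encodes the enzyme of the last steps to IMP, was at -1.94 ± 0.10, and *guaB* at -0.17 ± 0.09 (adjusted p = 0.161 in edgeR), or -0.39 (adjusted p = 0.00483) with library totals only. Among 18 salvage genes 8 were higher and *apt* was lower, also adjusted over the list alone (adjusted p = 0.0585 with an estimated correlation), and 8 were higher and 3 lower with library totals only. *deoB* (1.87 ± 0.07), *deoD* (1.45 ± 0.08) and *add* (1.36 ± 0.08) were higher as with MM6. The other 5 were the nucleoside breakdown and uptake genes *cdd* (1.25 ± 0.16), *deoC* (1.15 ± 0.13), *udp* (1.12 ± 0.12), *nupG* (0.77 ± 0.12) and *deoA* (0.57 ± 0.09). *ushA* did not pass (0.08 ± 0.08, 95% interval -0.086 to 0.253), and was at -0.13 with library totals only.

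Of 9 polyamine breakdown genes 4 were lower with MM3 (4 adjusted over the list alone, adjusted p = 0.621 with an estimated correlation), among them *puuA* (-1.23 ± 0.14), and none of 5 synthesis genes passed, also adjusted over the list alone (adjusted p = 0.831 with an estimated correlation). Their log2 fold changes lay between 0.0017 and 0.15, and *speE* was at 0.10 ± 0.10, or -0.12 with library totals only. Of the 11 transport and acetylation genes 4 were lower and 2 higher (5 and 3 adjusted over the list alone, adjusted p = 0.751 with an estimated correlation), with the exporter genes *mdtI* (-1.59 ± 0.15) and *mdtJ* (-1.53 ± 0.13) lowest; 6 were lower and 1 higher with library totals only. Of the genes tied to metabolites that MM3 did not contain, *glpD* fell (-1.12 ± 0.12, adjusted p = 3.83e-06 in edgeR), and *fbaB* did not pass (-0.21 ± 0.12, adjusted p = 0.192). *fbaB* was called with library totals only (-0.43, adjusted p = 0.0192) and without MM3 replicate 1 (-0.33, adjusted p = 0.0399).

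Of 54 ribosomal protein genes 52 rose with MM3 (52 adjusted over the list alone, adjusted p = 0.204 with an estimated correlation), with a median log2 fold change of 0.76 and the largest changes in *rpsQ* (1.65 ± 0.14) and *rplV* (1.16 ± 0.13), and 50 rose and 1 fell with library totals only. All 7 histidine synthesis genes rose (7 alone, adjusted p = 0.365 with an estimated correlation), by 0.95 ± 0.15 for *hisC* and 0.90 ± 0.12 for *hisD*. Of 12 genes for cysteine synthesis and sulfate assimilation 9 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.204 with an estimated correlation), led by the sulfate activation and uptake genes *cysD* (1.98 ± 0.24) and *cysP* (1.74 ± 0.33). Of 12 branched-chain amino acid genes 7 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.621 with an estimated correlation), against 5 and 3 with library totals only. Of 8 arginine synthesis genes 5 rose and 1 fell (7 and 1 alone, adjusted p = 0.252 with an estimated correlation), and 3 rose with library totals only. Examples were *argC* (1.06 ± 0.18) and *argF* (0.94 ± 0.21). Whether this strain carries a similar gene, *argI*, that could share reads with *argF* was not checked. Of 29 aerobic respiratory chain genes 14 rose and 1 fell (15 and 2 alone, adjusted p = 0.533 with an estimated correlation), but 4 rose and 5 fell with library totals only. With 1 library left out, 7 rose without control replicate 1, MM3 replicate 3 or MM3 replicate 4, 8 without control replicate 3 and 9 without MM3 replicate 2.

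Of 11 acid stress genes 8 fell with MM3 (9 adjusted over the list alone, adjusted p = 0.467 with an estimated correlation), led by the regulator genes *gadE* (-1.86 ± 0.36) and *gadW* (-1.55 ± 0.21); 5 fell without control replicate 3 or MM3 replicate 4. Of 13 nitrogen limitation genes 8 fell (8 alone, adjusted p = 0.338 with an estimated correlation), including the glutamine synthetase gene *glnA* (-1.14 ± 0.08). Of 24 anaerobic genes 2 rose, *frdA* (0.90 ± 0.14) and *ldhA* (0.72 ± 0.13), and *nirC* fell (-0.75 ± 0.15), also adjusted over the list alone (adjusted p = 0.78 with an estimated correlation); 4 rose without MM6 replicate 1 or MM6 replicate 2. Of 15 heat shock genes 6 fell (6 alone, adjusted p = 0.621 with an estimated correlation), and 12 with library totals only. Of 16 general stress genes 4 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.77 with an estimated correlation); 9 fell and 1 rose with library totals only, and 2 fell without control replicate 1, MM3 replicate 3 or MM3 replicate 4. Of 17 oxidative stress genes 4 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.621 with an estimated correlation), against 1 and 8 with library totals only.

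The third comparison set MM6 against MM3 and so asked what the mixture holding fructose 1,6-bisphosphate, dihydroxyacetone phosphate and UDP-glucose did beyond the mixture without them. The 3 were added together, so none was measured alone. Whether spermidine, GMP and IMP had equal concentrations in both mixtures is not given in the sources used here, so the contrast also holds any difference in these. Relative to MM3, 20 of 24 anaerobic respiration and fermentation genes were higher with MM6 and 1 was lower, and 11 of 12 branched-chain amino acid genes, all 7 histidine genes and 13 of 15 heat shock genes were lower, with 1 branched-chain amino acid gene higher. None of these lists was called by camera (adjusted p = 0.306, 0.369, 0.491 and 0.345 with an estimated correlation). Under the naming rule, the largest increases were in *napB* (3.78 ± 0.15), *nikC* (3.66 ± 0.29), *napH* (3.65 ± 0.22), *nikD* (3.34 ± 0.29) and *nikE* (3.26 ± 0.15), the last 2 being ATPase genes of the nickel transporter (log2 fold change with SE, n = 4 per group). In MM3 these genes had low means of 2.64, 2.26, 1.94, 4.62 and 4.26 CPM, in that order. They reached the mean of 10 CPM set by the rule only through MM6. The largest decreases under that rule were in *bioC* (-1.99 ± 0.12), *bioD* (ECHS_RS04070, a symbol that another gene of the table shares; -1.99 ± 0.13) and *bioF* (-1.87 ± 0.13) of biotin synthesis, in *nrdH* (-1.97 ± 0.12), which encodes a glutaredoxin-like electron donor of a ribonucleotide reductase, and in *ilvD* (-1.88 ± 0.16). Their edgeR adjusted p lay between 1.28e-10 for *napB* and 3.23e-07 for *nikD*.

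In all, 1716 genes (51.8%) differed, 908 higher and 808 lower with MM6, and 207 differed at least 2-fold (130 higher, 77 lower). The split was 938 higher and 704 lower with library totals only. At an unadjusted p under 0.05 there were 1915 genes, and without MM6 replicate 2 the test called 1898.

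**Figure D3:**
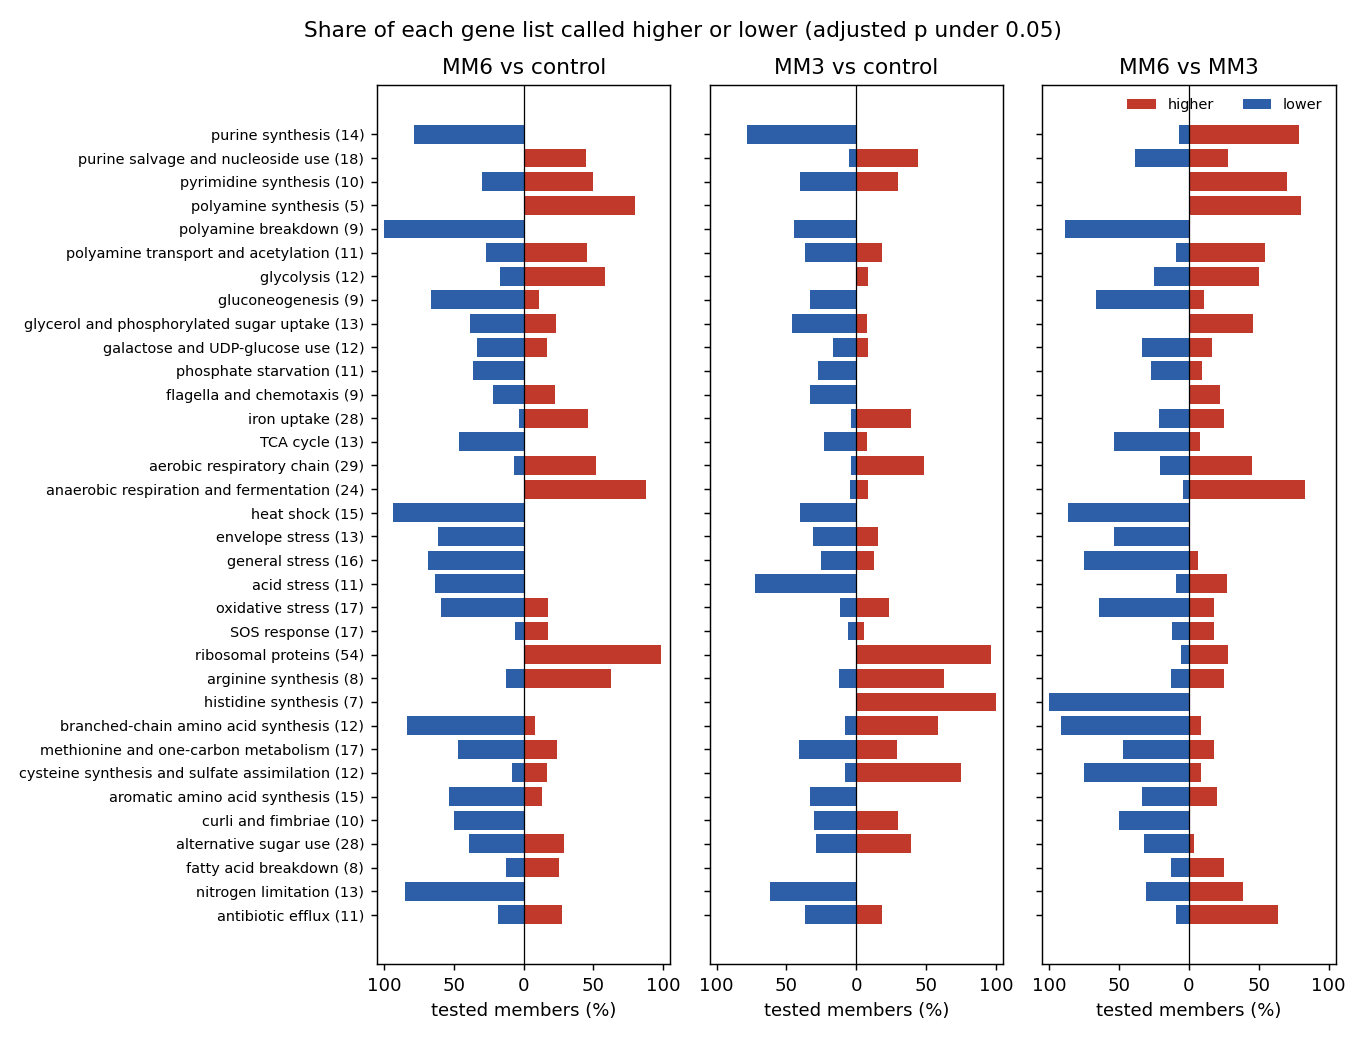
Share of the tested members of each of 34 gene lists that were called higher (red, to the right) or lower (blue, to the left) at an edgeR adjusted p under 0.05 in the 3 comparisons, with the number tested in parentheses. Anaerobic respiration and fermentation has 21 of 24 genes higher in MM6 against control, 2 in MM3 against control and 20 in MM6 against MM3.

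Of 24 anaerobic genes 20 were higher with MM6 than with MM3 and 1, *ldhA* of lactate fermentation (-0.66 ± 0.13), was lower (20 and 1 adjusted over the list alone, adjusted p = 0.306 with an estimated correlation), with the nitrite channel gene *nirC* (2.65 ± 0.14) and *frdC* (2.40 ± 0.21) at the top. Of 10 pyrimidine synthesis genes 7 were higher (7 alone, adjusted p = 0.306 with an estimated correlation), for instance *carA* (0.76 ± 0.11), a carbamoyl phosphate synthetase gene, and *pyrC* (0.73 ± 0.08), the dihydroorotase gene. Of 14 purine synthesis genes 11 were higher with MM6 than with MM3 and *guaA* (-0.21 ± 0.07) was lower (12 and 1 alone, adjusted p = 0.491 with an estimated correlation). Of the 11 that were lower than control in both mixtures 10 were among the higher ones, and *purL* did not pass (0.29 ± 0.12, adjusted p = 0.0579 in edgeR). *purK* (0.82 ± 0.12) and *purE* (0.81 ± 0.13) differed most. Of 18 salvage genes 5 were higher and 7 lower, also adjusted over the list alone (adjusted p = 0.491 with an estimated correlation), *cdd* (-1.48 ± 0.16) and *udp* (-1.35 ± 0.12) being lowest. *deoD* (-0.10 ± 0.08) and *ushA* (-0.14 ± 0.08) did not pass.

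Of 9 polyamine breakdown genes 8 were lower with MM6 than with MM3 (8 adjusted over the list alone, adjusted p = 0.357 with an estimated correlation), among them *puuB* (-1.80 ± 0.22), *puuC* (-1.63 ± 0.24) and *puuA* (-0.85 ± 0.15). Of 5 polyamine synthesis genes 4 were higher (4 alone, adjusted p = 0.491 with an estimated correlation), and of 11 transport and acetylation genes 6 were higher and 1 lower, also adjusted over the list alone (adjusted p = 0.491 with an estimated correlation), *plaP* being at 1.10 ± 0.12. *glpD* was higher (0.92 ± 0.12) and *fbaB* lower (-0.65 ± 0.12), with adjusted p of 1.14e-05 and 0.000516 in edgeR. *guaB* (0.23 ± 0.09, adjusted p = 0.0415), *speE* (0.26 ± 0.10, adjusted p = 0.0372) and *mdtJ* (0.33 ± 0.13, adjusted p = 0.0489) were called narrowly by edgeR. The call of *guaB* was lost without control replicate 1 (adjusted p = 0.0514), MM6 replicate 4 (0.154), MM3 replicate 1 (0.119), MM3 replicate 2 (0.0651) or MM3 replicate 3 (0.0687), and that of *speE* without MM6 replicate 2 (0.0921), MM3 replicate 1 (0.106) or MM3 replicate 2 (0.11). That of *mdtJ* was lost without control replicate 1 (0.061), control replicate 2 (0.0599), control replicate 3 (0.0536), control replicate 4 (0.0589), MM6 replicate 2 (0.147), MM6 replicate 4 (0.0539), MM3 replicate 1 (0.0592), MM3 replicate 2 (0.134) or MM3 replicate 3 (0.108), and each also with only the 8 libraries compared (0.0804, 0.0636 and 0.0903 in that order).

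Of 12 branched-chain amino acid genes 11 were lower with MM6 than with MM3 and *ilvB* (0.83 ± 0.16) was higher (11 and 1 adjusted over the list alone, adjusted p = 0.369 with an estimated correlation). *ilvD* was at -1.88 ± 0.16 and *ilvA*, the threonine deaminase gene, at -1.59 ± 0.18. All 7 histidine genes were lower (7 alone, adjusted p = 0.491 with an estimated correlation), with *hisD* at -0.81 ± 0.12 and *hisC* at -0.76 ± 0.15. Of 12 cysteine genes 9 were lower and *sbp* was higher, also adjusted over the list alone (adjusted p = 0.345 with an estimated correlation). Of 15 heat shock genes 13 were lower (13 alone, adjusted p = 0.345 with an estimated correlation), including *dnaK* (-0.89 ± 0.08) and the disaggregase gene *clpB* (-0.85 ± 0.09). Of 16 general stress genes 12 were lower and *wrbA* was higher (13 and 1 alone, adjusted p = 0.491 with an estimated correlation), against 10 lower and 0 higher with library totals only. Of 17 oxidative stress genes 11 were lower and 3 higher, also adjusted over the list alone (adjusted p = 0.306 with an estimated correlation). Of 54 ribosomal protein genes 15 were higher and 3 lower (14 and 3 alone, adjusted p = 0.878 with an estimated correlation); 10 were lower without MM6 replicate 2 and 13 without MM3 replicate 1.

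With the inter-gene correlation estimated for each list, limma's camera test called 0 of 34 lists in each of the 3 comparisons. The unadjusted p was under 0.05 for 5 lists in MM6 against control, 5 in MM3 against control and 3 in MM6 against MM3, and the smallest adjusted p were 0.243, 0.0585 and 0.306. With a preset correlation of 0.01 the test called 15, 10 and 11 lists, and none of these calls held with an estimated correlation, whose median over the lists was 0.187. The fry test, which asks whether the genes of a list move one way on balance and does not compare them with other genes, called 27, 24 and 25. The counts of members above rest on the tests of single genes.

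Both mixtures were compared with the same 4 control libraries. Against them, 647 genes changed in the same direction in both, 305 higher and 342 lower, and 108 changed in opposite directions. Independent lists of the same sizes would share 147.6 higher and 161.6 lower genes, and 100 simulations of unchanged groups against these controls shared 0 genes at the highest. None of these simulations called a gene in both comparisons, so that 0 sets no level for the overlap. The log2 fold changes correlated across genes with Pearson's r = 0.505, where genes are not independent replicates, and the simulated mean was 0.497. Shared controls give such an r even where nothing changed, so this r cannot tell a shared response from shared controls. The covariance was 0.141 against a simulated 0.00956, a difference of 0.132. With the controls split so that each mixture had its own pair, the 6 splits gave 406 to 464 shared genes, r of 0.435 to 0.507 and covariances of 0.126 to 0.144. With no control library shared, these values argue against noise of shared control libraries as the only source of the correlation. If the 4 control libraries came from 1 culture, both pairs would still share it. The splits therefore cannot tell a shared response from a deviation of the control culture. The genes that fell in both included 11 purine synthesis genes, and those that moved in opposite directions included *ilvD* (-0.90 ± 0.16 and 0.98 ± 0.16) and *nirC* (1.90 ± 0.13 and -0.75 ± 0.15).

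**Figure D4:**
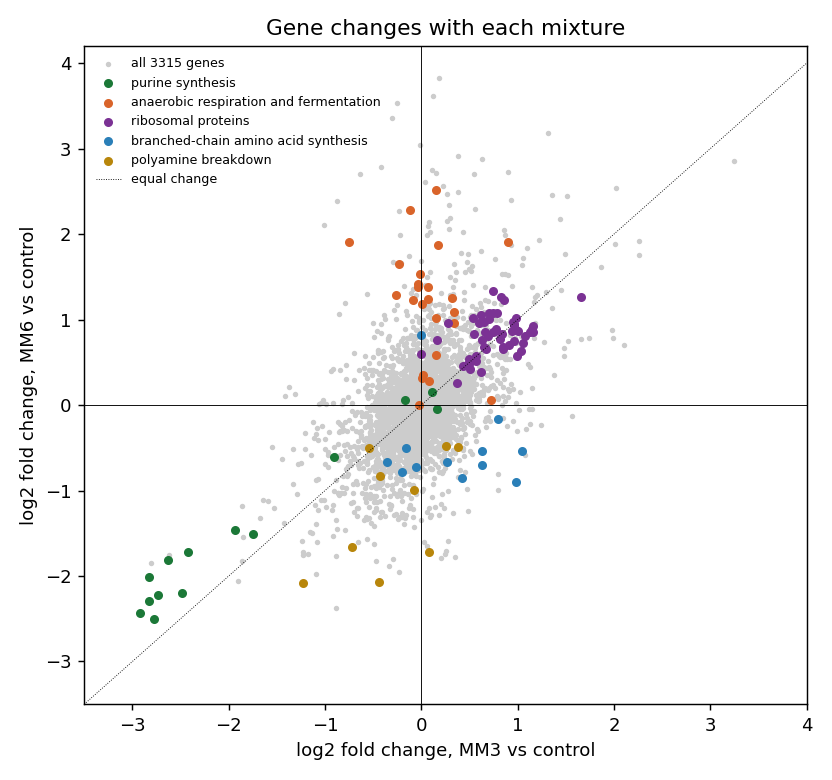
Log2 fold change with MM6 against that with MM3, both relative to the same controls, for all 3315 genes (grey) and for the members of 5 lists (coloured), with a dotted line of equal change. Ribosomal protein genes have medians of 0.85 with MM6 and 0.76 with MM3, and anaerobic respiration and fermentation genes have medians of 1.25 and 0.04.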

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

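The second test of whether MM6 replicate 2 belonged to another group was chosen after the result was seen; its first version and the test at equal totals were not.

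In 10 of 195 groups of 4 libraries, over 58 named genes and 7 measures of the libraries, 1 library lay apart from the other 3 by more than Dixon's 95% limit. Chance gives about 1 in 20 such groups, and 5.13% were found, all 10 for named genes. For *purN*, MM3 replicate 2 was at 82.1 CPM against 71.9 to 73.0 in the other MM3 libraries. For *purL*, control replicate 3 was at 860 CPM against 924 to 931, and MM3 replicate 1 was at 126 CPM against 171 to 176. For *leuC*, control replicate 3 was at 127 CPM against 151 to 155. For *guaB*, MM6 replicate 4 was at 351 CPM against 276 to 285. For *ushA*, MM3 replicate 4 was at 78.1 CPM against 86.2 to 86.3. For *speE*, MM6 replicate 2 was at 525 CPM against 406 to 426. For *glpD*, control replicate 2 was at 58.3 CPM against 72.5 to 73.5. For *ilvA*, MM3 replicate 1 was at 212 CPM against 305 to 309, and for *purE* it was at 27.6 CPM against 34.8 to 36.1.

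MM6 replicate 2 differed from the other MM6 libraries by a median absolute log2 difference of 0.26 to 0.30, where these differed from one another by 0.10 to 0.16. A lower depth was argued against by the totals, since MM6 replicate 2 held 7617531 counts and MM6 replicate 1 fewer, 7360791. With every MM6 library thinned to 7360791 counts, the lowest difference of MM6 replicate 2 was 0.27 and the highest between the others 0.173. MM6 replicate 2 lost few counts by this thinning, which therefore adds little. A library of another group was argued against too, since over 1398 genes that parted MM6 from both other groups it lay 0.885 of the way from MM3 and 0.894 of the way from control to the other MM6 libraries. No control library lay further than 0.0399 and no MM3 library further than 0.0511. These libraries helped to choose the genes and set the starting points, so their positions were low by construction and are no reference. A first test had found MM6 replicate 2 nearest to the other MM6 libraries for 64.2% of the 1398 genes, between the bounds set beforehand. No biological explanation was tested, and a difference in the culture or in the preparation of the library stays open.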

How the results depend on the processing

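Of the settings for the deposited counts, the removal of the 10 most counted genes was chosen after the data were seen, and the smallest simulated fold was lowered to 1.2 after a first simulation, which had recovered a larger share of genes at its larger fold. The number of changed genes moved by less than 1.5 times from 1782, 1151 and 1716 (MM6 against control, MM3 against control, MM6 against MM3) under every setting that kept the test at any fold change, and no gene was called in opposite directions. It was 1775, 1147 and 1707 with RLE factors, 1765, 1145 and 1718 with upper-quartile factors, 1955, 1647 and 1642 with library totals only, 1713, 1125 and 1628 with the stricter filter, 1838, 1225 and 1792 with DESeq2, 1797, 1160 and 1702 with limma voom, 1638, 1525 and 1510 with only the 8 libraries compared, and 1757, 1135 and 1713 without the 10 most counted genes. With 1 library left out it was 1606 to 1964, 924 to 1488 and 1485 to 1898, the highest each time without MM6 replicate 2. With library totals only, 571 genes were higher and 1384 lower in MM6 and 274 higher and 1373 lower in MM3 than in control, where that scaling shifted the median log2 fold change of all genes by -0.19 and -0.22. At 2-fold or more there were 320 (173 higher, 147 lower), 118 (56, 62) and 207 (130, 77). A preset correlation called 15, 10 and 11 lists and fry 27, 24 and 25, against 0 with an estimated correlation. Between the mixtures, 647 shared calls became 406, 406, 413, 415, 443 and 464 with split controls, which leaves fewer libraries per test, 694 with DESeq2, 591 with the block and 527 to 838 with 1 library left out, the highest without MM6 replicate 2.

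Replicate numbers did not pair the libraries, since 1 of 12 pairs of libraries correlated above 0.1 in their deviations and 0 of 12 libraries correlated best with their own number. The replicate block gave 1687, 1031 and 1585 genes, and of the named genes it ended the calls of *guaB* (adjusted p = 0.0614), *speE* (0.0534) and *mdtJ* (0.0879) between MM6 and MM3 in edgeR.

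These log2 fold changes, none of them called, changed sign, and the cause was not tested. With library totals only, in MM6 against control, *guaB* was at -0.13, and in MM3 against control *ushA* was at -0.13 and *speE* at -0.12. With 1 library left out, *guaB* in MM6 ranged from -0.027 (without MM6 replicate 4) to 0.097. Between MM6 and MM3 *mdtJ* was not called with RLE factors (adjusted p = 0.0537) or limma voom (0.0682). With no filter every value was as reported, which tests nothing, since the filter used removed 0 genes. Of the list counts of 2 or fewer, 39 moved by over 1.5 times with 1 library left out, 33 of them by 1 gene. With 4 libraries per group of 6676778 to 11166478 counts, edgeR recovered 14 to 20% of genes changed 1.2-fold in simulated counts. Only 200 of 3315 simulated genes were changed, where 1151 to 1782 were called in the data, so the adjustment of p-values was stricter in the simulation. The share of such changes detectable in the data was thus not measured. Some were called, such as *speE* between MM6 and MM3 (1.19-fold, adjusted p = 0.0372 in edgeR). What depth alone limits was not simulated.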

Other observations

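For the higher anaerobic genes in MM6, the tests without MM6 replicate 2 and for less oxygen were chosen after the result was seen, as was the test for stationary phase in the ribosomal protein genes and the setting without the 10 most counted genes. The number of list members that stayed called was also computed after their counts had been seen.

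The other carbon and respiration lists are given for MM6 against control, MM3 against control and MM6 against MM3 in that order. Of 13 TCA cycle genes there were 0 higher and 6 lower (the same adjusted over the list alone, adjusted p = 0.738 with an estimated correlation), 1 higher and 3 lower (the same adjusted over the list alone, adjusted p = 0.913 with an estimated correlation) and 1 higher and 7 lower (the same adjusted over the list alone, adjusted p = 0.743 with an estimated correlation), with 6 lower in MM3 with library totals only and a median of 0.04 in MM3 where the test pointed down. The citrate synthase gene *gltA* was at -1.29 ± 0.10, -0.38 ± 0.10 and -0.91 ± 0.10. The aerobic chain had 13 higher and 6 lower (the same adjusted over the list alone, adjusted p = 0.866 with an estimated correlation) between the mixtures. Glycolysis had 1 higher and 0 lower (the same adjusted over the list alone, adjusted p = 0.855 with an estimated correlation) in MM3 and 6 higher and 3 lower (7 and 3 adjusted over the list alone, adjusted p = 0.775 with an estimated correlation) between the mixtures, where 1 gene was lower without MM3 replicate 1 or MM3 replicate 2. Gluconeogenesis had 0 higher and 3 lower (the same adjusted over the list alone, adjusted p = 0.464 with an estimated correlation) in MM3, with 6 lower with library totals only and 1 without control replicate 2, MM3 replicate 1 or MM3 replicate 4, and 1 higher and 6 lower (the same adjusted over the list alone, adjusted p = 0.491 with an estimated correlation) between the mixtures. Uptake of glycerol and phosphorylated sugars had 1 higher and 6 lower (the same adjusted over the list alone, adjusted p = 0.464 with an estimated correlation) and 6 higher and 0 lower (the same adjusted over the list alone, adjusted p = 0.491 with an estimated correlation). Galactose and UDP-glucose use, with 12 genes, had 2 higher and 4 lower (2 and 3 adjusted over the list alone, adjusted p = 0.516 with an estimated correlation), 1 higher and 2 lower (the same adjusted over the list alone, adjusted p = 0.78 with an estimated correlation) (0 and 5 with library totals only) and 2 higher and 4 lower (the same adjusted over the list alone, adjusted p = 0.61 with an estimated correlation). Of 28 genes for other sugars there were 8 higher and 11 lower (8 and 12 adjusted over the list alone, adjusted p = 0.381 with an estimated correlation), 11 higher and 8 lower (12 and 8 adjusted over the list alone, adjusted p = 0.77 with an estimated correlation) and 1 higher and 9 lower (the same adjusted over the list alone, adjusted p = 0.345 with an estimated correlation), with a median of 0.15 and a mean of -0.06 in MM3. The maltose transport gene *malK* fell in both mixtures (-2.05 ± 0.14 and -1.91 ± 0.13) and the fructose gene *fruB* rose (1.32 ± 0.14 and 1.29 ± 0.14). Of 8 fatty acid breakdown genes there were 2 higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.806 with an estimated correlation), 0 higher and 0 lower (the same adjusted over the list alone, adjusted p = 0.871 with an estimated correlation) and 2 higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.866 with an estimated correlation), with 3 lower in MM6 without MM6 replicate 3 and 0 without control replicate 1 or MM6 replicate 4. Of 28 iron uptake genes there were 13 higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.368 with an estimated correlation), 11 higher and 1 lower (12 and 1 adjusted over the list alone, adjusted p = 0.442 with an estimated correlation) and 7 higher and 6 lower (the same adjusted over the list alone, adjusted p = 0.876 with an estimated correlation); with library totals only the first 2 became 7 and 3, and 7 and 6, and 11 were higher between the mixtures without MM6 replicate 2. The iron(II) transporter gene *feoB* was at 2.40 ± 0.20, 0.93 ± 0.19 and 1.47 ± 0.19. Genes outside the lists, chosen after their values were seen, included the anaerobic ribonucleotide reductase gene *nrdD* (2.04 ± 0.20) and *ompW* (2.88 ± 0.19), higher in MM6, and *nrdE* (-1.82 ± 0.10 in MM6 and -0.47 ± 0.10 in MM3) and *nrdF* (-1.80 ± 0.15 and -0.30 ± 0.15) of another ribonucleotide reductase.

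The other lists, in the same order, were as follows. Of 10 pyrimidine synthesis genes there were 5 higher and 3 lower (the same adjusted over the list alone, adjusted p = 0.564 with an estimated correlation) and 3 higher and 4 lower (the same adjusted over the list alone, adjusted p = 0.468 with an estimated correlation), with 1 lower in MM6 without control replicate 1, control replicate 2, control replicate 3 or MM6 replicate 3, and 1 higher in MM3 without control replicate 4, MM3 replicate 2, MM3 replicate 3 or MM3 replicate 4, and 0 with library totals only. Arginine synthesis had 5 higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.328 with an estimated correlation) in MM6 and 2 higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.878 with an estimated correlation) between the mixtures. Histidine synthesis had 0 higher and 0 lower (the same adjusted over the list alone, adjusted p = 0.806 with an estimated correlation) in MM6, and cysteine synthesis 2 higher and 1 lower (2 and 0 adjusted over the list alone, adjusted p = 0.867 with an estimated correlation), with 4 higher without MM6 replicate 4. Of 17 methionine and one-carbon genes there were 4 higher and 8 lower (the same adjusted over the list alone, adjusted p = 0.368 with an estimated correlation), 5 higher and 7 lower (the same adjusted over the list alone, adjusted p = 0.73 with an estimated correlation) and 3 higher and 8 lower (the same adjusted over the list alone, adjusted p = 0.491 with an estimated correlation), with 2 higher in MM6 without MM6 replicate 4 and 5 lower between the mixtures without MM3 replicate 2 or MM3 replicate 3. The serine hydroxymethyltransferase gene *glyA* fell in both mixtures (-1.32 ± 0.08 and -1.68 ± 0.09) and the S-adenosylmethionine synthetase gene *metK* rose (1.27 ± 0.12 and 1.18 ± 0.12). Of 15 aromatic amino acid genes there were 2 higher and 8 lower (2 and 10 adjusted over the list alone, adjusted p = 0.243 with an estimated correlation), 0 higher and 5 lower (the same adjusted over the list alone, adjusted p = 0.344 with an estimated correlation) (0 and 12 with library totals only) and 3 higher and 5 lower (the same adjusted over the list alone, adjusted p = 0.491 with an estimated correlation), the last with 1 higher and 3 lower without MM3 replicate 2 and 3 lower without MM3 replicate 3. Nitrogen limitation had 5 higher and 4 lower (5 and 5 adjusted over the list alone, adjusted p = 0.925 with an estimated correlation) between the mixtures. Of 13 envelope stress genes there were 0 higher and 8 lower (the same adjusted over the list alone, adjusted p = 0.381 with an estimated correlation), 2 higher and 4 lower (3 and 4 adjusted over the list alone, adjusted p = 0.855 with an estimated correlation) (1 and 8 with library totals only) and 0 higher and 7 lower (the same adjusted over the list alone, adjusted p = 0.491 with an estimated correlation), and the periplasmic chaperone gene *spy* rose in MM3 (1.56 ± 0.14). Acid stress had 3 higher and 1 lower (2 and 1 adjusted over the list alone, adjusted p = 0.87 with an estimated correlation) between the mixtures, with 1 higher without MM6 replicate 2, MM6 replicate 4, MM3 replicate 2, MM3 replicate 3 or MM3 replicate 4 and 5 without MM6 replicate 3. Of 17 SOS genes there were 3 higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.806 with an estimated correlation), 1 higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.525 with an estimated correlation) and 3 higher and 2 lower (the same adjusted over the list alone, adjusted p = 0.866 with an estimated correlation), with 1 and 5 in MM6 with library totals only, and without MM6 replicate 2 with 4 higher in MM3 and 5 higher and 4 lower between the mixtures. In MM3, 2 SOS genes were higher without MM6 replicate 1, MM3 replicate 1 or MM3 replicate 4. Of 11 phosphate starvation genes there were 0 higher and 4 lower (the same adjusted over the list alone, adjusted p = 0.328 with an estimated correlation), 0 higher and 3 lower (the same adjusted over the list alone, adjusted p = 0.365 with an estimated correlation) (0 and 6 with library totals only) and 1 higher and 3 lower (the same adjusted over the list alone, adjusted p = 0.743 with an estimated correlation). Of 9 flagella genes tested there were 2 higher and 2 lower (the same adjusted over the list alone, adjusted p = 0.756 with an estimated correlation), 0 higher and 3 lower (0 and 4 adjusted over the list alone, adjusted p = 0.452 with an estimated correlation) and 2 higher and 0 lower (the same adjusted over the list alone, adjusted p = 0.801 with an estimated correlation); in MM3, 1 was lower without control replicate 1, 5 without MM6 replicate 2 and 6 with library totals only. Of 10 curli and fimbriae genes there were 0 higher and 5 lower (the same adjusted over the list alone, adjusted p = 0.343 with an estimated correlation) (0 and 9 with library totals only), 3 higher and 3 lower (the same adjusted over the list alone, adjusted p = 0.915 with an estimated correlation) and 0 higher and 5 lower (the same adjusted over the list alone, adjusted p = 0.369 with an estimated correlation), with 1 higher in MM3 without control replicate 1, control replicate 3, control replicate 4, MM3 replicate 2 or MM3 replicate 4. Of 11 antibiotic efflux genes there were 3 higher and 2 lower (the same adjusted over the list alone, adjusted p = 0.756 with an estimated correlation), 2 higher and 4 lower (3 and 5 adjusted over the list alone, adjusted p = 0.621 with an estimated correlation) and 7 higher and 1 lower (7 and 2 adjusted over the list alone, adjusted p = 0.345 with an estimated correlation), with a median of -0.02 in MM6 where the test pointed up. In MM3, 4 were higher without MM6 replicate 2 and 1 without control replicate 1, control replicate 3, MM3 replicate 2, MM3 replicate 3 or MM3 replicate 4. With library totals only, the counts higher and lower that moved by over 1.5 times also included, in MM6, flagella (2 and 5), cysteine synthesis (2 and 4), antibiotic efflux (2 and 4), galactose use (1 and 6), aromatic amino acids (1 and 12), methionine (2 and 10) and fatty acid breakdown (2 and 2). In MM3 they included glycolysis (1 and 2), glycerol uptake (0 and 7), methionine (3 and 8), antibiotic efflux (1 and 6), SOS (0 and 1), curli (0 and 4) and fatty acid breakdown (0 and 2), and between the mixtures aromatic amino acids (3 and 3). The regulator gene *marA* rose in both mixtures (1.64 ± 0.16 and 1.05 ± 0.16).

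For the numbers of changed genes, 1 of 35 splits of each 8 libraries, the real one, gave as many. It gave 1782 genes for MM6 against control, 1151 for MM3 against control and 1716 for MM6 against MM3. The highest other split gave 0 each time. A share of 1 of 35 is the lowest these splits can give, so chance in the grouping is made less likely but is not excluded. Every other split mixed libraries of the groups compared, so its 0 is no measure of the spread between like cultures. Since the replicates may be technical, the splits cannot tell an effect of the metabolites from a chance difference between cultures. For lists the count of splits decides nothing, since camera called 0 in the real split and 0 in the highest other of each comparison, so that 35 of 35 splits gave as many. For the overlap of the mixtures it decides nothing either: 1 of 100 regroupings of the 12 libraries, the real one, shared 647 genes and the highest other 0, but 0 of the other 99 called any gene in both comparisons, so none could share one.

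In MM6, 21 of 24 tested anaerobic respiration and fermentation genes, of 40 listed, were higher than in control (adjusted p = 0.243 with an estimated correlation), in cultures grown aerobically with shaking per the labels. Library scaling was argued against, since at least 19 of the 21 stayed called higher under the 3 other scalings, and so was MM6 replicate 2 as the source, since 20 of them stayed called higher without it. Less oxygen in the MM6 cultures stays open: of 26 genes that cells turn down when oxygen runs short, 12 were lower in MM6 than in control and 0 higher, with a median of -0.30 and a fry p of 0.0152 in limma. Between MM6 and MM3, 14 of them were lower and 2 higher, and between MM3 and control 7 were lower and 3 higher, for which limma's fry test gave p-values of 0.0456 and 0.483. Fry does not compare a list with other genes. It called 27 of the 34 lists in MM6 against control, 25 in MM6 against MM3 and 24 in MM3 against control. Its unadjusted p-values therefore mark nothing particular to these 26 genes, for which camera was not run. As no values of oxygen or density were used here, less oxygen and an effect of the added metabolites cannot be told apart, and either may contribute.

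Ribosomal protein genes were higher than in control in both mixtures, 53 of 54 in MM6 and 52 in MM3 (adjusted p = 0.243 and 0.204 with an estimated correlation). Library scaling was argued against, since at least 51 of these in MM6 and 50 in MM3 stayed called higher under the 3 other scalings. With the 10 most counted genes removed, all 53 and 52 stayed called higher. That removal shifted the median log2 fold change of all genes by only 0.015 in MM6 and 0.013 in MM3. The medians of the ribosomal protein genes were 0.85 and 0.76, so these calls could hardly be lost and the removal decides little. The 10 most counted genes of each library held 23.3 to 29.4% of its counts, so they did not take most of them. Control cultures further toward stationary phase stay open: of 16 general stress genes, which rise as growth slows, 11 were lower and 0 higher in MM6, and 4 lower and 2 higher in MM3 (adjusted p = 0.357 and 0.77 with an estimated correlation), where 2 were lower without control replicate 1, MM3 replicate 3 or MM3 replicate 4. With library totals only, 12 were lower and 0 higher in MM6, and 9 lower and 1 higher in MM3. The submitters placed the sampling in mid-exponential growth before any difference in growth, which speaks against controls nearer stationary phase. No culture density was used here, so such a difference in growth phase and an effect of the metabolites cannot be told apart. Gene length and GC content were not tested, as no genome of this strain was used here.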
